A study of Mus musculus with 12 samples.

How the data were processed

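Gene expression was measured by biotin-labelled oligonucleotide arrays in 12 samples of total RNA from mouse neural cells lacking p53. The samples fall into 6 groups of 2 arrays each, taken from the sample titles. NSC are neural stem cells, OPC are oligodendrocyte precursor cells and AST are astrocytes, and NSCL61, OPCL61 and ASTL61 are the stable lines made from them with an oncogenic form of HRas (HRasL61). Per the labels' protocols, the stem cells came from the telencephalon of embryonic day 14.5 mice of the BL6 strain and were grown without serum as floating spheres. Astrocytes were induced from them by 10% fetal calf serum over 3 weeks. OPC were induced with PDGFAA, bFGF and 0.25% serum and purified by sequential immunopanning. Per the series design text, the lines were made by electroporation with a plasmid carrying HRasL61 and EGFP and another carrying neomycin resistance, then kept in 0.5 mg/ml neomycin and sorted for GFP. RNA was extracted on silica columns, and 5 µg of it was labelled by a one-cycle in vitro transcription, per the labels' protocols.

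The deposited values are log2 signals per probe set, already made by the authors. The table holds 45101 probe sets, of which 64 are array controls, with no missing value and a range from 2.139 to 14.33. The background correction, summarisation and normalisation are not given in the sources used here. Array medians lay between 5.157 and 5.211, a range of 0.05335, which is inside the limit of 0.25 set for using the values as deposited. No pseudocount was needed, since the values are already logarithmic. The number of arrays limits the precision.

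Gene names came from a table of the array's probe sets. It lists 35890 probe sets, of which 34958 have 1 gene symbol and 932 have several, and no gene name was used for 9160 others that are not controls. For 34754 of the probe sets with 1 symbol the Entrez identifier was found in a RefSeq gene table of mouse assembly GRCm38.p6, which changed 0 symbols. That table was used for symbols and for which genes share a chromosome and neighbour each other, and no coordinates are given because the value table names no genome build. A probe set was kept where its mean in at least 1 group lay above 5.183, the median of all values. Control probe sets and those with no symbol or several symbols were left out of the gene tests. A gene with several kept probe sets, as 6097 had, was represented by the probe set with the highest mean over the 12 arrays. This left 12835 genes. The Hras and Trp53 transcripts, planned as a check of the introduced and the disrupted gene, were not analysed here.

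All 12 arrays were fitted in a single linear model of 6 group means in limma 3.58.1 under R 4.3.3, with the data.table package, version 1.17.8, for reading the files. The model has 6 residual degrees of freedom, and 9.302 in total after limma's empirical Bayes moderation. Each comparison is a contrast of group means, with 2-sided p-values adjusted over the 12835 genes by the Benjamini-Hochberg method and a threshold of 0.05. Fold changes are log2 differences ± the moderated standard error (SE), and group values are means ± SD with n = 2. Where a group lies under 5.183, its signal may be background. The size of a fold change to or from it may then be a lower bound, and its rank is uncertain. The 3 main comparisons set each HRasL61 line against its parent. Further contrasts gave the average of the 3, the differences between their changes, the parental cell types against each other and the lines against each other. The 28 gene lists hold markers of cell types and members of pathways, and 26 of them were tested for a shift against all other genes with limma's camera, at a preset correlation between genes of 0.01. The 78 tests of 26 lists in 3 comparisons were adjusted together. Counts of list members past the threshold were also adjusted over the list alone.

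The grouping, the model, the filter, the gene lists, the rule for naming genes and most alternatives were chosen before the data were examined. By that rule the text names, for each main comparison, the 8 largest rises and the 8 largest falls past the threshold whose arrays do not overlap between the groups, leaving out provisional symbols. It also names up to 3 members of each list past the threshold with the smallest p, or where none passed the member with the smallest p. Cell type comparisons and differences between lines take 5 genes each way. Hras, Trp53, Ptgs2, Egfr, Sox11, Olig2, Cdkn2a, Gfap, Nes and Mki67 could be named anywhere. Genes named outside the rule are said to have been chosen after their values were seen.

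The alternatives were quantile normalisation, centring each array on its median, no filter, a filter at the 75th percentile of all values (7.562), the mean of a gene's probe sets, a replicate block, a trended robust prior, array weights, a model of only the arrays compared, a fold change of at least 2 (a log2 change of 1), an estimated correlation between genes in camera, and leaving out each array in turn. Added after seeing the data were a covariate for the signal of the 5' probe set of 18S ribosomal RNA and averages over 2 of the 3 lines. Replicate numbers were checked for pairing. Over 15 pairs of groups, the correlation across genes of the differences between replicates ran from -0.196 to 0.105, so no pairing was assumed. The labels do not say whether the 2 arrays of a group come from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

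The model was tested on simulated data of the same size, with changes added to 200 of the 12835 genes. A change of 2-fold was called in 76.1% of such genes for NSCL61 against NSC, 71.6% for OPCL61 against OPC and 56.7% for ASTL61 against AST. Each share rests on 67 genes. A change of 1.5-fold was called in 26.9%, 29.9% and 29.9%, and a change of 4-fold in 97.0%, 97.0% and 98.5%. The order at 2-fold was not kept at 1.5-fold or 4-fold. Each gene was simulated with a single mean and a single spread for all arrays, while the real groups differed in spread. The simulated comparisons thus differed only in the random draw, and differences between their shares say nothing about the comparisons. Whether changes are harder to call in ASTL61 could not be shown this way. The simulated list shift was called in each comparison, and 0 other lists were. How often camera calls unshifted lists whose members vary together was not tested. Genes without an added change made up 7.48%, 6.94% and 1.59% of the calls.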

Results

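The series compares 3 kinds of neural cell from mice lacking p53, each with and without an oncogenic HRas. The parents were neural stem cells (NSC), oligodendrocyte precursor cells (OPC) and astrocytes (AST), and the lines carrying HRasL61 were NSCL61, OPCL61 and ASTL61. Per the series title, the lines stand for glioma-initiating cells. The lines were also electroporated, kept in neomycin and sorted for GFP, steps not given for the parents. No array of parents taken through those steps is there. HRasL61 and those steps therefore cannot be told apart in a comparison of a line with its parent. A change with HRasL61 below means the line against its parent. Each of the 6 groups holds 2 arrays, and 12835 genes were tested. Array medians lay between 5.157 and 5.211 on the log2 scale. Differences between the 2 arrays of a group had an SD over genes of 0.193 in NSCL61, 0.253 in AST, 0.282 in OPC, 0.372 in ASTL61, 0.415 in OPCL61 and 0.416 in NSC. The signal of the 5' probe set of 18S ribosomal RNA, a control on the array, was 7.906 and 12.13 in the NSC arrays, 8.060 and 11.67 in NSCL61, and 8.708 and 12.59 in OPC. It lay between 8.422 and 10.29 in the other 6 arrays.

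Marker genes set OPC apart from the other parents, while NSC and AST differed in some and shared others. Olig1 and Olig2, transcription factors of the oligodendrocyte lineage, had levels of 13.95 ± 0.13 and 12.27 ± 0.05 (mean ± SD, n = 2) in OPC, and Olig2 had 2.82 ± 0.19 in NSC and 2.91 ± 0.14 in AST. Sox2, a transcription factor of neural stem cells, had 5.60 ± 1.69 in NSC, with 4.407 and 6.790 in the 2 arrays, against 11.94 ± 0.07 in OPC and 10.19 ± 0.17 in AST. The NSC arrays were instead high in genes known from fibroblasts and pericytes. Col1a1 (collagen I) had 12.77 ± 0.23 in NSC, 4.21 ± 0.19 in OPC and 11.13 ± 0.54 in AST. Thy1 had 10.54 ± 0.28 in NSC and 3.91 ± 0.14 in AST. Acta2, smooth muscle actin, had 13.66 ± 0.02 in NSC, 9.38 ± 1.45 in OPC and 13.47 ± 0.19 in AST. Gfap, the intermediate filament of astrocytes, had 5.57 ± 0.22 in AST, 6.90 ± 1.17 in OPC and 5.06 in NSC. Other probe sets of Gfap gave 3.86 and 3.20 in AST, 6.07 and 6.64 in OPC, and 3.71 and 3.42 in NSC. Those AST and NSC values lie under 5.183 and may be background. These levels stand beside every comparison that uses the NSC or AST arrays.

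**Figure D1:**
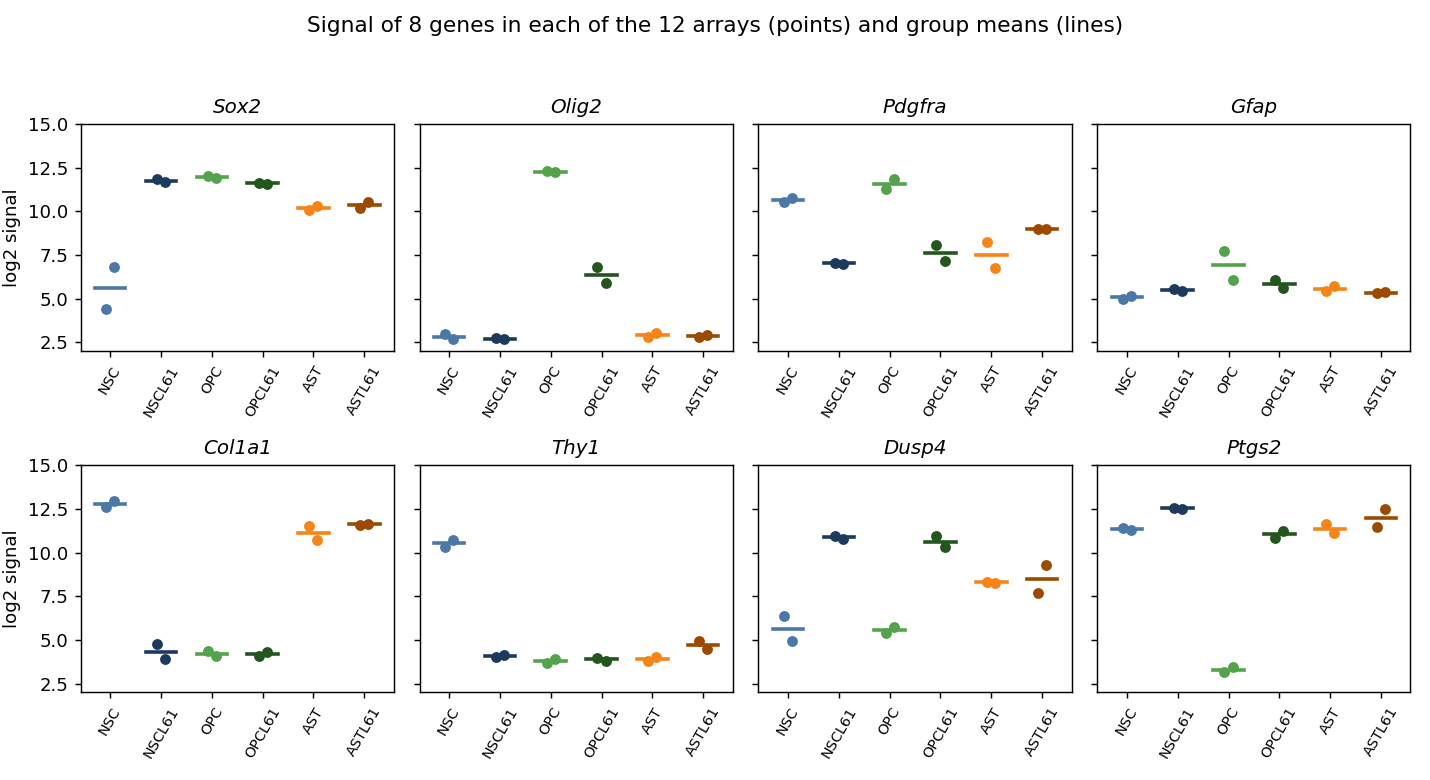
Log2 signal of 8 genes in each array (points) with the mean of each group (lines), for the 6 groups of 2 arrays. Sox2 lies at 4.407 and 6.790 in the NSC arrays and at a mean of 11.75 in NSCL61, while Col1a1 falls from a mean of 12.77 in NSC to 4.31 in NSCL61.

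The comparison of OPC with NSC asks how these cell types differed before HRasL61 was added. OPC were higher for Olig1 by 9.94 ± 0.17 (log2 fold change ± SE; adjusted p = 8.49e-10), Olig2 by 9.45 ± 0.25, the membrane glycoprotein Gpm6a by 8.85 ± 0.12, the endothelin receptor Ednrb by 8.68 ± 0.31 and the fatty acid binding protein Fabp7 by 8.63 ± 0.49. The NSC signals of Olig1 (4.260 and 3.762) and Olig2 (2.961 and 2.686) may be background, so both changes may be lower bounds. S100a6, a calcium-binding protein, differed by -10.15 ± 0.14 (adjusted p = 2.99e-10) and the annexin Anxa1 by -9.80 ± 0.17. Ccn2, the collagen cross-linking enzyme Lox and Col5a2 differed by -9.46 ± 0.25, -9.42 ± 0.24 and -9.22 ± 0.18. Of 17 measured OPC markers, 13 were higher and 1 lower in OPC (14 and 1 adjusted over the list alone). Of 16 astrocyte markers, 13 were higher and 1 lower (13 and 1 adjusted over the list alone), among them Acsbg1 by 6.32 and S100b by 4.44. Of 12 pericyte and fibroblast genes, 11 were lower and 0 higher by limma (12 and 0 adjusted over the list alone). The Sox family had 10 of 11 members higher (10 adjusted over the list alone). In all, 6612 genes passed the test, 3495 higher and 3117 lower in OPC.

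AST differed from NSC in fewer genes, 3904, of which 1976 were higher and 1928 lower in AST. Higher in AST were cardiac troponin T (Tnnt2) by 5.46 ± 0.52, Plscr2 by 5.30 ± 0.33, the hydroxylase Cyp7b1 by 5.11 ± 0.47, the neural transcription factor Pou3f3 by 5.06 ± 0.23 and Ces1g by 4.96 ± 0.56. Lower were the matrix protein Aspn at -8.35 ± 0.24, Thy1 at -6.63 ± 0.19, Lrrc17 at -6.42 ± 0.30, the sulfatase Sulf1 at -6.33 ± 0.17 and Actg2 at -6.28 ± 0.21. The astrocyte list did not part them: 2 of 16 members were lower in AST, Sox9 at -1.24 and Apoe at -3.19, and 0 were higher by limma (2 and 0 adjusted over the list alone). Of 12 pericyte and fibroblast genes, 9 were lower in AST (9 adjusted over the list alone). Of 14 neural stem cell genes, 4 were higher in AST (4 adjusted over the list alone), among them Lhx2 by 4.18 and Sox2 by 4.59. Of 28 cell cycle genes, 17 were higher in AST (19 adjusted over the list alone). The count of 3904 was 2368 without AST replicate 1 and 2123 without AST replicate 2.

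OPC and AST differed in 6637 genes, 3354 higher and 3283 lower in OPC. OPC were higher for Olig1 by 10.37 ± 0.17, Fabp7 by 9.75 ± 0.49 and Olig2 by 9.37 ± 0.25. S100a6 differed by -10.16 ± 0.14, Cd34 by -8.27 ± 0.92 and the proteoglycan Bgn by -8.13. Of 17 OPC markers, 15 were higher in OPC (15 adjusted over the list alone), and of 16 astrocyte markers 13 were higher and 1 lower (13 and 1 adjusted over the list alone). Of 14 cholesterol synthesis genes, 8 were higher (9 adjusted over the list alone). Of 19 inflammatory cytokine and chemokine genes, 13 were lower in OPC (14 adjusted over the list alone).

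The comparison of NSCL61 with NSC asks how the HRasL61 line differed from its neural stem cell parent. The largest rises were those of Bex1 by 8.01 ± 0.93 (adjusted p = 1.61e-04), the polysialyltransferase St8sia4 by 7.81 ± 0.39 (adjusted p = 1.04e-06), the adhesion molecule Nrcam by 7.37 ± 0.48, the protocadherin Pcdh8 by 7.22 ± 0.28 and the neurofilament light chain Nefl by 6.52 ± 0.23. The growth factor binding protein Igfbp3, the interleukin 5 receptor chain Il5ra and the neuropeptide receptor Qrfpr rose by 7.54 ± 0.28, 7.33 ± 0.17 and 6.66 ± 0.13. The largest falls were those of Lox, collagens and other proteins of the extracellular matrix. Lox changed by -9.04 ± 0.24 (adjusted p = 2.35e-08), Col5a2 by -8.95 ± 0.18, Mgp by -8.53 ± 0.54, Col1a1 by -8.46 ± 0.30, Col1a2 by -8.41 ± 0.20, Efemp1 by -8.33 ± 0.44, Aspn by -8.31 ± 0.24 and Bgn by -8.02 ± 0.15. In all, 4851 genes passed the test, 2657 higher and 2194 lower in NSCL61, and the count was 3012 without NSCL61 replicate 1.

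Stem cell genes rose as a set in NSCL61. Of 14 measured, 7 rose, 0 fell by limma and 7 did not pass (7 and 0 adjusted over the list alone; camera adjusted p = 0.0150), and adjusted p = 0.234 with an estimated correlation. Sox2 rose by 6.15 ± 0.57, from 5.60 ± 1.69 to 11.75 ± 0.13, Prom1, which encodes the stem cell antigen CD133, by 4.87 ± 0.28, and the Lewis X fucosyltransferase Fut4 by 3.03 ± 0.17. The Sox family rose as well, with 5 of 11 members higher and 0 lower (5 and 0 adjusted over the list alone), for example Sox6 by 2.17 ± 0.22. Its camera adjusted p was 0.0281, adjusted p = 0.310 with an estimated correlation, and 0.0539 with the filter at the 75th percentile (range over the alternatives 0.00389 to 0.310). The pericyte and fibroblast list fell, with 9 of 12 members lower and 0 higher (9 and 0 adjusted over the list alone; camera adjusted p = 7.14e-08), and adjusted p = 0.208 with an estimated correlation. Thy1 changed by -6.45 ± 0.19 and the platelet-derived growth factor receptor Pdgfrb by -7.15 ± 0.21. These genes, like the collagens, were high in both NSC arrays. Gfap, at 0.43 ± 0.42 (adjusted p = 0.463), and Olig2, at -0.12, did not pass.

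Among pathways, MAPK output, genes switched on downstream of Ras signalling, rose as a set. Of 20 members, 14 rose, 1 fell and 5 did not pass (15 and 1 adjusted over the list alone; camera adjusted p = 0.00104), and adjusted p = 0.584 with an estimated correlation. The feedback inhibitors Dusp4, Spry4 and Spred3 rose by 5.22 ± 0.53, 3.97 ± 0.39 and 2.01 ± 0.21. Of 28 cell cycle genes, 10 rose, 0 fell and 18 did not pass (10 and 0 adjusted over the list alone), for example the replication licensing factor Cdc6 by 1.02 ± 0.22. The camera adjusted p was 0.0114, and adjusted p = 0.824 with an estimated correlation. Mki67, a marker of dividing cells, was at 0.08 ± 0.24 (adjusted p = 0.829). Of 14 cholesterol synthesis genes, 8 fell and 0 rose (8 and 0 adjusted over the list alone), for example Hmgcs1 at -1.56 ± 0.26. Its camera adjusted p was 0.0130, and adjusted p = 0.780 with an estimated correlation, and without NSC replicate 2 it was 0.140 (range over the alternatives 6.91e-04 to 0.780). Of 14 Wnt pathway genes, 6 fell and 1 rose (7 and 1 adjusted over the list alone). The inhibitors Dkk3 and Sfrp2 changed by -4.42 ± 0.14 and -4.43 ± 0.27, and the ligand Wnt7b by 3.90 ± 0.13. Its camera adjusted p was 0.0257, and adjusted p = 0.315 with an estimated correlation. It was 0.116 without NSC replicate 1 and 0.107 with the filter at the 75th percentile (range over the alternatives 0.00249 to 0.315).

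Other lists did not pass camera's threshold in NSCL61 with the settings used, though some members passed the gene test. Of 17 OPC markers, 5 fell (5 adjusted over the list alone), including Pdgfra at -3.62 ± 0.44, the proteoglycan Cspg4 at -1.69 ± 0.16 and Ptprz1 at -2.36 ± 0.31. Of 11 mature oligodendrocyte genes, 2 rose (2 adjusted over the list alone), Ugt8a by 4.15 ± 0.46 and Aspa by 1.77 ± 0.27. Of 16 astrocyte genes 2 rose and 2 fell (2 and 1 adjusted over the list alone), with Acsbg1 at 3.04 ± 0.26. Of 15 neuronal genes 4 rose and 3 fell (4 and 3 adjusted over the list alone), with Nefm at 5.38 ± 0.49 and the tubulin Tubb3 at -3.15 ± 0.36. Of 7 EGF family genes 3 rose and 1 fell (4 and 1 adjusted over the list alone), with the ligands Btc at 3.91 ± 0.44 and Ereg at 3.27 ± 0.57. Egfr was at -0.07 ± 0.17 (adjusted p = 0.789), and another probe set of Egfr gave -1.75. Of 10 prostaglandin genes 3 rose and 2 fell (3 and 2 adjusted over the list alone), the latter being the prostacyclin synthase Ptgis at -5.81 ± 0.21 and the phospholipase Pla2g4a at -2.69 ± 0.17. Of 17 mesenchymal genes 6 fell and 1 rose (6 and 1 adjusted over the list alone), with the transcription factors Snai1 at -2.93 ± 0.32 and Snai2 at -2.03 ± 0.29. Of 11 matrix proteases 4 fell and 2 rose (4 and 2 adjusted over the list alone), with Mmp2 at -5.23 ± 0.38.

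For signalling and regional genes in NSCL61, 5 of 7 Hedgehog genes fell and 1 rose (5 and 1 adjusted over the list alone), with Gli2 at -3.58 ± 0.28 and Hhip at 1.47 ± 0.17. The camera adjusted p of that list was 0.0540, and over the alternatives it ran from 0.0104 to 0.339, with 9 of 21 settings past the threshold. Of 10 Notch genes 4 rose (4 adjusted over the list alone), with the target Nrarp at 1.06 ± 0.16. The camera adjusted p passed in 1 of 21 settings for the Notch list (0.0363 to 0.780) and in 1 of 21 for the mesenchymal list (0.0396 to 0.584). Of 12 BMP and Id genes 2 rose and 4 fell (2 and 4 adjusted over the list alone), with Bmp4 at -2.83 ± 0.18 and Bmp2 at 3.62 ± 0.51. Of 14 hypoxia and glycolysis genes 6 rose and 1 fell (6 and 1 adjusted over the list alone), with the glucose transporter Slc2a1 at 1.44 ± 0.18. Of 10 telencephalic transcription factors 3 rose and 3 fell (3 and 4 adjusted over the list alone), with Lhx2 at 2.89 ± 0.37 and Dlx2 at -1.55 ± 0.20. Of 19 inflammatory genes 6 rose and 5 fell (6 and 5 adjusted over the list alone), with the chemokine Cxcl12 at -5.11 ± 0.29 and Il11 at 2.58 ± 0.30. Of 8 CDK inhibitor genes 2 rose and 2 fell (2 and 3 adjusted over the list alone), with Cdkn2c at -0.91 ± 0.11 and Cdkn1b at -0.97 ± 0.17. Cdkn2a was at -0.67 ± 0.24 (adjusted p = 0.0525). The median, the mean and the camera direction differed in sign for the astrocyte, neuron, BMP, interferon, inflammatory and telencephalic lists.

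The comparison of OPCL61 with OPC asks the same of oligodendrocyte precursors. S100a6 had the largest measured rise, by 9.60 ± 0.14 (adjusted p = 6.25e-10), from 3.44 ± 0.08 in OPC to 13.04 ± 0.27 in OPCL61. Its OPC level lay under 3.91, the highest group mean of the Y-linked probe sets, so the rise may be a lower bound. Anxa1 rose by 8.73 ± 0.17, the membrane protein Tm4sf1 by 8.36 ± 0.33, the metalloprotease inhibitor Timp1 by 8.01 ± 0.44 and Ptgs2, the inducible prostaglandin synthase, by 7.75 ± 0.30. Ptgs2 lay at 3.174 and 3.422 in the OPC arrays, so its rise may be a lower bound too. The retinoic acid binding protein Crabp1, the natriuretic peptide Nppb and the reductase Akr1b8 rose by 7.49 ± 1.01, 7.31 ± 0.19 and 6.94 ± 0.17. Gpm6a fell most, at -7.85 ± 0.12 (adjusted p = 9.02e-10). Lrrn1 changed by -7.27 ± 0.21, Rlbp1 by -6.81 ± 0.14, Bcas1, a gene of oligodendrocytes starting to make myelin, by -6.79 ± 0.17, Ndn by -6.68 ± 0.26, Scrg1 by -6.65 ± 0.17, Spon1 by -6.45 ± 0.21 and Pcdh15 by -6.34 ± 0.21. In all, 6219 genes passed the test, 3146 higher and 3073 lower in OPCL61.

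Markers of the oligodendrocyte lineage fell together in OPCL61. Of 17 OPC markers, 15 fell, 0 rose by limma and 2 did not pass (15 and 0 adjusted over the list alone; camera adjusted p = 4.72e-10), and adjusted p = 0.234 with an estimated correlation. Olig1 changed by -4.92 ± 0.17 and Olig2 by -5.91 ± 0.25, the latter from 12.27 ± 0.05 to 6.36 ± 0.65. Sox10, a member of this list and of the Sox list, was chosen after its values were seen. It was at -0.17 with the probe set used, and other probe sets gave -0.84 and -2.27. Of 11 mature oligodendrocyte genes, 7 fell and 1 rose (8 and 1 adjusted over the list alone), with the myelin genes Mbp at -3.97 ± 0.28 and Cnp at -3.15 ± 0.21, and Aspa at 4.05 ± 0.27. Its camera adjusted p was 0.0150, adjusted p = 0.421 with an estimated correlation, and 0.199 with the filter at the 75th percentile (range over the alternatives 0.00173 to 0.421). Of 16 astrocyte genes, 11 fell and 2 rose (12 and 2 adjusted over the list alone; camera adjusted p = 1.89e-04), and adjusted p = 0.234 with an estimated correlation. S100b changed by -4.61 ± 0.21, the glutamate transporter Slc1a2 by -3.80 ± 0.24 and Atp1b2 by -3.98 ± 0.27. Of 11 Sox genes, 8 fell and 0 rose (8 and 0 adjusted over the list alone; camera adjusted p = 4.26e-04), and adjusted p = 0.208 with an estimated correlation. Sox3, Sox6 and Sox8 changed by -4.40 ± 0.11, -4.39 ± 0.22 and -4.78 ± 0.32.

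The MAPK output, mesenchymal, hypoxia and glycolysis, and inflammatory lists rose in OPCL61. Of 20 MAPK output genes, 13 rose and 2 fell (13 and 2 adjusted over the list alone; camera adjusted p = 0.0114), and adjusted p = 0.673 with an estimated correlation. Fosl1, an AP-1 subunit, rose by 5.28 ± 0.31, Hmga2 by 4.76 ± 0.34 and the ephrin receptor Epha2 by 2.88 ± 0.25. Of 17 mesenchymal genes, 12 rose and 3 fell (12 and 3 adjusted over the list alone; camera adjusted p = 0.0150), and adjusted p = 0.421 with an estimated correlation. The hyaluronan receptor Cd44 rose by 3.89 ± 0.26 and Twist1 by 2.24 ± 0.21. Of 14 hypoxia and glycolysis genes, 11 rose and 0 fell (11 and 0 adjusted over the list alone; camera adjusted p = 6.73e-04), and adjusted p = 0.478 with an estimated correlation. Slc2a1, Ndrg1 and the phosphofructokinase Pfkp rose by 2.33 ± 0.18, 4.34 ± 0.40 and 2.16 ± 0.21. Of 19 inflammatory genes, 11 rose and 0 fell (11 and 1 adjusted over the list alone; camera adjusted p = 0.00483), and adjusted p = 0.421 with an estimated correlation. The chemokine Ccl2 rose by 6.12 ± 0.38, the cytokine Lif by 4.61 ± 0.48 and Tnfaip3, an inhibitor of NF-kB, by 1.75 ± 0.21.

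Other lists did not pass camera's threshold in OPCL61 with the settings used. Of 14 stem cell genes 5 fell and 1 rose (5 and 1 adjusted over the list alone), with Hes5 at -3.46 ± 0.14 and Prom1 at 4.79 ± 0.28. Of 15 neuronal genes 6 fell and 3 rose (6 and 3 adjusted over the list alone), with Nefl at 6.57 ± 0.23 and Elavl3 at -2.76 ± 0.21. Of 12 pericyte and fibroblast genes 2 rose and 1 fell (1 and 1 adjusted over the list alone), with Acta2 at -3.25 ± 0.52. Of 7 EGF family genes 2 rose and 2 fell (2 and 2 adjusted over the list alone), with the receptor Erbb3 at -3.22 ± 0.12 and the ligand Hbegf at 3.34 ± 0.40. Egfr was at -0.58 with the probe set used, and its other probe sets ran from -3.91 to 0.11. Of 10 prostaglandin genes 5 rose and 1 fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.0540), with the receptor Ptgfr at 3.81 ± 0.21. That p ran from 0.0254 to 0.646 over the alternatives, with 3 of 21 past the threshold. Of 28 cell cycle genes 5 rose and 2 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.377, from 0.0363 to 0.925 over the alternatives). Without OPC replicate 1 that p was 0.0363 (range over the alternatives 0.0363 to 0.925). Of 8 CDK inhibitor genes 2 rose and 2 fell (3 and 4 adjusted over the list alone), with Cdkn2a at 2.21 ± 0.24 and Cdkn2c at -1.37 ± 0.11. Of 11 matrix proteases 4 rose (4 adjusted over the list alone), with the urokinase receptor Plaur at 5.48 ± 0.37. Of 10 Notch genes 4 fell (4 adjusted over the list alone; camera adjusted p = 0.0540), with Dll3 at -5.45 ± 0.27. Over the alternatives the p of the Notch list ran from 0.0104 to 0.584, with 6 of 21 past the threshold.

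Among the remaining lists in OPCL61, 3 of 14 Wnt genes fell and 2 rose (3 and 2 adjusted over the list alone), with the receptor Lgr5 at -2.24 ± 0.14. Of 7 Hedgehog genes 1 rose and 1 fell (1 and 1 adjusted over the list alone), with the receptor Ptch1 at -1.57 ± 0.29. Of 12 BMP and Id genes 4 rose and 3 fell (4 and 3 adjusted over the list alone), with the antagonist Grem1 at 4.05 ± 0.46 and Bmp4 at -1.49 ± 0.18. Of 14 cholesterol synthesis genes 1 fell (0 adjusted over the list alone). Of 10 telencephalic transcription factors 2 rose and 1 fell (2 and 1 adjusted over the list alone), with Nr2f2 at 2.65 ± 0.10. Gfap was at -1.08 ± 0.42 (adjusted p = 0.0581) with the probe set used, and other probe sets gave -1.84 and -3.36. The median, the mean and the camera direction differed in sign for the neuron, EGF family, CDK inhibitor and telencephalic lists.

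**Figure D2:**
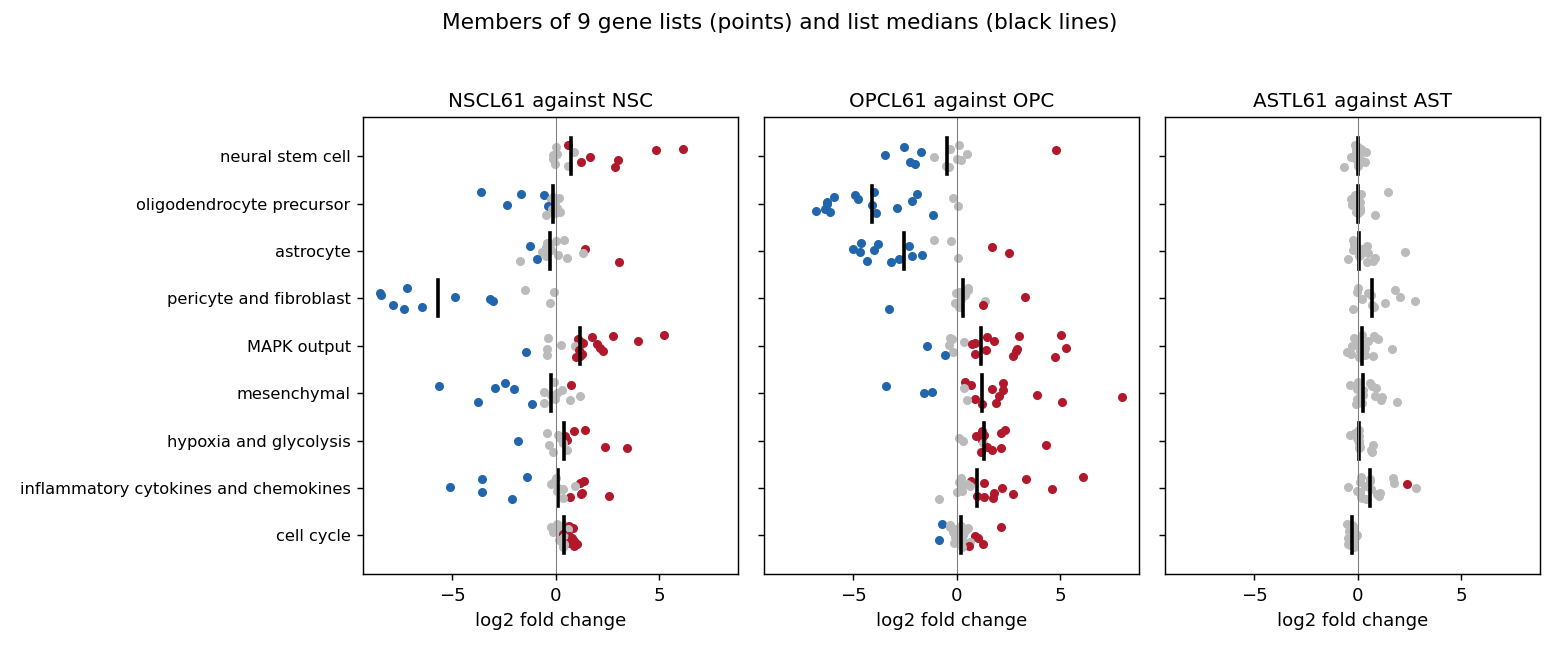
Log2 fold change of each measured member (points) of 9 gene lists in each HRasL61 line against its parent, with members past the test in red (higher) or blue (lower), others in grey, and the list median as a black line. The pericyte and fibroblast list has a median of -5.66 in NSCL61, and the oligodendrocyte precursor list has a median of -4.06 in OPCL61.

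The comparison of ASTL61 with AST asks the same of astrocytes, and 3 genes passed the test, all higher in ASTL61. The chemokine receptor Ackr3 rose by 3.00 ± 0.34 (adjusted p = 0.0383), from 4.80 ± 0.41 to 7.81 ± 0.61. The chemokine Cxcl5 rose by 2.39 ± 0.25 (adjusted p = 0.0232), and Cxcl3 by 2.14 ± 0.20 (adjusted p = 0.0181). Cxcl3 had low signals, 3.500 and 3.026 in AST and 5.304 and 5.510 in ASTL61, and passed the filter only through ASTL61. At an unadjusted p under 0.05 limma gave 941 genes. The median absolute log2 fold change over genes was 0.128, against 0.328 in NSCL61 and 0.426 in OPCL61. Sparcl1 was at 2.29 ± 0.54 (adjusted p = 0.322), Pdgfra at 1.47 ± 0.44 (adjusted p = 0.453) and Gfap at 5.34 ± 0.04 in ASTL61 beside 5.57 ± 0.22 in AST. Other probe sets of Gfap had 3.80 and 3.04 in ASTL61 beside 3.86 and 3.20 in AST. The count was 0 without either NSCL61 array, either OPC array or AST replicate 2, and 1 without either OPCL61 array or ASTL61 replicate 2. It was 6 without either NSC array, 17 without AST replicate 1 and 102 without ASTL61 replicate 1.

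Several lists shifted slightly in ASTL61, by camera. The inflammatory list rose (adjusted p = 8.85e-07), and adjusted p = 0.234 with an estimated correlation. Of its 19 members 1 passed, Cxcl5, and 5 were higher adjusted over the list alone. The pericyte and fibroblast list rose (adjusted p = 5.84e-05), and adjusted p = 0.234 with an estimated correlation. It had 0 of 12 members past the test and 5 higher adjusted over the list alone, with Fbln1 at 1.34 ± 0.21 (adjusted p = 0.137). The prostaglandin list rose (adjusted p = 9.11e-05), and adjusted p = 0.315 with an estimated correlation. It had 0 of 10 members past the test and 4 higher adjusted over the list alone, with Ptgis at 1.53 ± 0.21 (adjusted p = 0.0795). The cell cycle list shifted downward by a median of -0.257 (adjusted p = 4.41e-07), adjusted p = 0.587 with an estimated correlation, and 0.342 without ASTL61 replicate 2 (range over the alternatives 1.13e-11 to 0.587). It had 0 of 28 members past the test, and 0 adjusted over the list alone, with E2f1 at -0.45 ± 0.15 (adjusted p = 0.537).

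The cholesterol synthesis list also shifted downward in ASTL61 (camera adjusted p = 9.11e-05), adjusted p = 0.652 with an estimated correlation, and 0.382 without AST replicate 2 (range over the alternatives 1.59e-09 to 0.652). It had 0 of 14 members past the test, and 0 adjusted over the list alone. The matrix proteases shifted upward (adjusted p = 0.0114), adjusted p = 0.421 with an estimated correlation, and 0.404 without ASTL61 replicate 2 (range over the alternatives 0.00169 to 0.421). They had 0 of 11 members past the test, and 0 adjusted over the list alone, with Mmp2 at 1.11 ± 0.38 (adjusted p = 0.547). The mesenchymal list shifted upward (adjusted p = 0.0188), adjusted p = 0.421 with an estimated correlation. It was 0.167 without AST replicate 2 and 0.106 without ASTL61 replicate 2 (range over the alternatives 0.00358 to 0.421). It had 0 of 17 members past the test, and 0 adjusted over the list alone. MAPK output had 0 of 20 members past the test (0 adjusted over the list alone; camera adjusted p = 0.126), with the feedback inhibitor Spry2 at 0.97 ± 0.38 (adjusted p = 0.633). Without ASTL61 replicate 1 that p was 2.23e-04, with an upward direction (range over the alternatives 2.23e-04 to 0.824). The EGF family, with 0 of 7 members past the test (0 adjusted over the list alone), had a camera adjusted p of 0.0664, and 0.0118 without ASTL61 replicate 1 (range over the alternatives 0.00304 to 0.421). For the other lists in ASTL61, 0 members passed by limma over all genes and camera gave adjusted p values of 0.0679 or more. The lowest, that of the interferon and antigen presentation list with an upward direction, ran from 0.00947 to 0.780 over the alternatives and passed in 10 of 21. Adjusted over the list alone, 2 Wnt genes were higher, as was 1 gene each of the astrocyte, CDK inhibitor, BMP and telencephalic lists. The median, the mean and the camera direction differed in sign for the neural stem cell, neuron, p53 target, Hedgehog and Sox lists.

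NSCL61 and OPCL61 shared part of their change. Of the 12835 genes, 1218 rose in both against 651 expected of independent lists, and 817 fell in both against 525 expected. Another 746 changed in opposite directions against 1174 expected. The fold changes of the 2 lines had a correlation across genes of 0.225, and genes are not independent replicates. Without NSCL61 replicate 1, 1281 genes changed in the same direction in both lines, against 2035 with all arrays. As 0 genes passed the limma test in all 3 lines, the shared genes named here were chosen after their values were seen. Nefl rose by 6.52 and 6.57 in NSCL61 and OPCL61, Qrfpr by 6.66 and 6.44, the keratin Krt76 by 5.96 and 6.56, and the sodium-proton exchanger Slc9a2 by 5.55 and 5.63. Col11a1 changed by -5.34 and -4.58. Averaged over the 3 lines, Dusp4 rose by 3.48 ± 0.30 (adjusted p = 2.86e-05), Prom1 by 3.19 ± 0.16, Cdh11 changed by -2.77 ± 0.30 and Pdgfra by -2.04 ± 0.26. In ASTL61 alone these 4 were at 0.19, -0.08, 0.70 and 1.47, with 0 past the test. The average passed the test in 5609 genes, 2935 higher and 2674 lower with HRasL61.

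**Figure D3:**
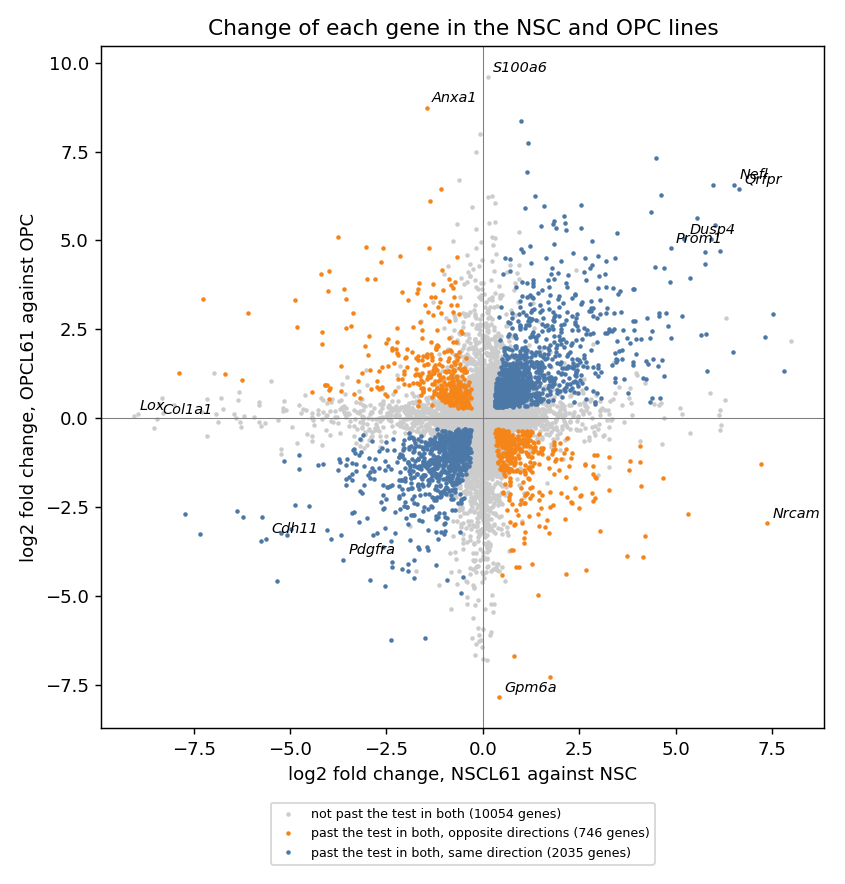
Log2 fold change of each tested gene (points) in NSCL61 against NSC (horizontal axis) and in OPCL61 against OPC (vertical axis). The 2035 genes past the test in both with the same direction are blue, the 746 with opposite directions are orange, and the others are grey.

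The lines were compared with each other to ask how they differ after HRasL61. OPCL61 and NSCL61 differed in 3423 genes, 1704 higher and 1719 lower in OPCL61. The homeobox gene Rhox5 was higher by 6.21 ± 0.12, Fabp7 by 6.03 ± 0.49, Olig1 by 5.59 ± 0.17 and the keratin Krt6a by 5.32 ± 0.22. The protease Ctsz differed by -8.97 ± 0.14, the galectin Lgals3 by -7.80 ± 0.44, Ereg by -7.70 ± 0.57, Plp2 by -7.12 ± 0.14 and Ndn by -7.01 ± 0.26. Of 14 cholesterol synthesis genes 8 were higher in OPCL61 (9 adjusted over the list alone), of 20 MAPK output genes 3 were higher and 3 lower (3 and 3 adjusted over the list alone), and of 17 OPC markers 4 were higher (4 adjusted over the list alone). The count was 1798 without NSCL61 replicate 1 and 1866 without NSCL61 replicate 2.

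ASTL61 and NSCL61 differed in 4197 genes, 2069 higher and 2128 lower in ASTL61. Lox was higher in ASTL61 by 8.40 ± 0.24, Bgn by 7.61 ± 0.15 and Col1a2 by 7.55 ± 0.20. Il5ra differed by -7.45 ± 0.17 and Nefl by -6.86. Of 20 MAPK output genes 9 were lower in ASTL61 and 1 higher (12 and 1 adjusted over the list alone), with Spry4 at -5.03 and the phosphatase Dusp6 at -2.90. Of 19 inflammatory genes 14 were higher and 1 lower (14 and 1 adjusted over the list alone), with Cxcl12 at 5.50 and Cxcl5 at 5.33. The count was 2433 without NSCL61 replicate 1 and 2666 without NSCL61 replicate 2. OPCL61 and ASTL61 differed in 4702 genes, 2428 higher and 2274 lower in OPCL61. Nefl was higher in OPCL61 by 9.01 ± 0.23, Rhox5 by 8.14 ± 0.12 and Nefm by 6.61, and Lox and the caveolin Cav1 differed by -8.71 ± 0.24 and -7.32 ± 0.22. Of 20 MAPK output genes 13 were higher in OPCL61 and 3 lower (14 and 3 adjusted over the list alone). Of 14 cholesterol synthesis genes 11 were higher (12 adjusted over the list alone), with Dhcr7 at 2.45, and of 19 inflammatory genes 12 were lower and 1 higher (12 and 1 adjusted over the list alone).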

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

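The tests of exchanged labels, of the share of stem cell RNA and of a wider spread between arrays were chosen only after the result was seen.

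The change with HRasL61 differed between NSC and OPC in 4868 genes by limma's test of the difference, 2558 with the higher change in NSCL61 and 2310 with the higher change in OPCL61. The values that follow are the change in NSCL61 minus the change in OPCL61, on the log2 scale. Nrcam stood at 10.32 ± 0.68 (SE), having risen in NSCL61. Lrrn1 stood at 9.03, Pcdh8 at 8.50, Gpm6a at 8.28 and Ugt8a at 8.05. At the other end were Cavin2 at -10.63 ± 1.42, Anxa1 at -10.18, S100a6 at -9.47, the matrix protein Postn at -9.16 and Lox at -9.11. Such a difference equals the gap between the parents minus the gap between their lines. For S100a6, Anxa1, Lox and Gpm6a it was close to the gap of OPC from NSC given above. For these genes the parents lay far apart and the lines close together. The values therefore do not show a response to HRasL61 apart from the state of the parents.

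Between OPC and AST the change differed in 4545 genes, 2199 with the higher change in OPCL61. The change in OPCL61 minus the change in ASTL61 was 9.56 for S100a6, 8.54 for Anxa1, 7.53 for Tm4sf1, 7.16 for Nppb and 7.14 for Ptgs2. It was -7.96 for Gpm6a, -7.16 for Lrrn1, -6.95 for Sparcl1, -6.90 for Bcas1 and -6.78 for Rlbp1. S100a6 differed between the parents by a similar amount, being lower in OPC than in AST, as given above.

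Between NSC and AST the change differed in 3252 genes, 1660 with the higher change in NSCL61. The change in NSCL61 minus the change in ASTL61 was 8.76 for Bex1, 7.31 for St8sia4, 7.20 for Il5ra, 7.15 for Pcdh8 and 6.91 for Nrcam. It was -10.71 for Mgp, -10.70 for Efemp1, -9.58 for Lox, -9.05 for Col1a2 and -8.98 for Col5a2. The count was 2023 without NSCL61 replicate 1, 2153 without NSCL61 replicate 2 and 2080 without AST replicate 2.

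Probe sets with no gene name used were outside the comparisons. Of 2090 such probe sets tested, 381 (18.2%) passed in NSCL61 against NSC, with changes up to 6.86 and down to -5.69. In OPCL61 against OPC 717 (34.3%) passed, with changes up to 6.84 and down to -7.90, and in ASTL61 against AST 0 passed, with changes between -1.05 and 2.43.

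The NSC arrays were high in fibroblast genes, with Col1a2 at 13.73 ± 0.10 and Acta2 at 13.66 ± 0.02, and low in Sox2, so the falls of matrix genes and the rise of stem cell genes in NSCL61 both rest on the state of its parent. Exchanged labels of the NSC and AST arrays are argued against, since the AST arrays had the higher mean correlation over genes with the ASTL61 arrays, 0.984 against 0.934, a difference of 0.0501, although they were also closer than the NSC arrays to NSCL61, 0.896 against 0.859, as an exchange would also give, and NSC arrays from another source stay open. Stem cells outnumbered by fibroblasts in the NSC arrays remain a candidate explanation: with the Sox2 level of NSCL61 taken for pure stem cells, Sox2 allows at most 3.21% of stem cell RNA in an NSC array, and by the same reckoning Prom1 allows 4.59% but Nes 71.1% and Hes1 138%, so the list sets no single share. This cannot be told apart from stem cells that themselves had little Sox2 and much collagen mRNA, because no array of a pure parental stem cell is there to compare, and the GFP sort of NSCL61 selects carriers of the plasmid and not a cell type. A change of the same genes by HRasL61 also stays open, untested.

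ASTL61 differed from AST in 3 genes by limma, and in 0 to 102 with 1 array left out, the most being without ASTL61 replicate 1 (941 genes at an unadjusted p under 0.05 with all arrays). A wider spread that hides changes as large as in the other lines is argued against, since the median absolute log2 fold change was 0.391 of the smaller of those in the other lines, and a wider spread would make it larger. Parental astrocytes in ASTL61 replicate 1 stay open, although growth in neomycin and the sort for GFP select against them: over all genes it correlated at 0.9940 and 0.9875 with the AST arrays and at 0.9842 with the other ASTL61 array, against 0.9928 between the AST arrays. Its median position over the 102 genes, 0.241 on a scale from the AST mean at 0 to the other ASTL61 array at 1, decides nothing because they were picked for their difference in that other array, so parental cells and cells with a weaker change cannot be told apart. A smaller response of the AST cells to HRasL61 stays open, untested. The AST arrays were themselves low in the astrocyte list, with a median level of 5.63 against 9.74 in OPC and 6.27 in NSC. Their pericyte and fibroblast list had a median level of 7.43, and 9.17 in ASTL61, against 10.9 in NSC and 4.33 in OPC. What cells the AST label stands for stays open as well.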

How the results depend on the processing

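The covariate for the 18S signal and the averages over 2 of the 3 lines were tests chosen only after the data were seen. Leaving out an array leaves its group with 1, which is then assumed to vary like the other groups. The named genes were picked from these same data, mostly for a large change or a small p. How they fared therefore does not show how a typical gene fares. Of 726 values of named genes, quantile normalisation left 722 with their direction and side of the threshold, median centring 723, no filter 714, the mean of probe sets 711, the replicate block without pairing of arrays 721, the trended robust prior 722, array weights 720, only the arrays compared 682 and the 18S covariate 707. With the filter at the 75th percentile 651 of 653 did. Of 8712 values with an array left out 8353 did, 346 lost and 13 gained the call and 0 reversed. The 3 reversals came with no filter, where another probe set stands for the gene: Dcx in OPC against NSC was at -0.0201, Sox1 in OPCL61 against NSCL61 at -0.246 and Sox1 in OPCL61 against ASTL61 at -0.187. Of 78 list tests, quantile normalisation and the robust prior left all 78 as they were, centring, the mean of probe sets and the block 76 each, the 18S covariate 74 and no filter 71, the rest gaining a call. With the filter at the 75th percentile 70 of 75 kept theirs, 3 lost and 2 gained a call. The filter left out genes with no group mean above 5.183, so genes low in all but 1 group stayed in. Without it 18193 genes were tested. Quantile normalisation and centring moved the median fold change of a comparison by at most 0.025 and 0.034.

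Requiring a log2 fold change of at least 1 allows fewer genes by construction. It left 641 of the 726 values as they were and gave 2099 genes in NSCL61 against NSC, 2810 in OPCL61 against OPC and 1033 for the average. For the differences between lines it gave 3097 (NSC and OPC), 2792 (OPC and AST) and 2063 (NSC and AST). It gave 3161 for OPC against NSC, 1335 for AST against NSC, 3080 for OPC against AST, 1321 for OPCL61 against NSCL61, 1702 for ASTL61 against NSCL61 and 1843 for OPCL61 against ASTL61, and 691 genes shared by NSCL61 and OPCL61. Of the 1335 genes, 33.6% were higher in AST, against 50.6% of all 3904. ASTL61 against AST gave 5 genes with array weights, 0 with only the arrays compared and 0 with the 18S covariate, where limma's main model gave 3 and 941 at an unadjusted p under 0.05. OPCL61 against ASTL61 gave 2598 genes with only the arrays compared, where fewer arrays give the spread. The lists shifted were 7, 8 and 7 for NSCL61, OPCL61 and ASTL61 with camera's preset correlation and 0, 0 and 0 with an estimated correlation, which widens the test for lists whose members vary together. For the array weights, the 18S covariate and the other calls that moved the cause was not tested.

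With each array left out in turn, the counts ran from 3012 to 5140 for NSCL61 against NSC, 4637 to 6296 for OPCL61 against OPC, 0 to 102 for ASTL61 against AST and 4645 to 5666 for the average. Differences between lines ran from 3684 to 4958 (NSC and OPC), 3298 to 4637 (OPC and AST) and 2023 to 3576 (NSC and AST). OPC against NSC ran from 5229 to 6834, AST against NSC from 2123 to 4196, OPC against AST from 5210 to 6897, OPCL61 against NSCL61 from 1798 to 3502, ASTL61 against NSCL61 from 2433 to 4468, and OPCL61 against ASTL61 from 3692 to 4773. Shared genes ran from 1281 to 2079, and lists shifted from 6 to 8, 8 to 10 and 5 to 9. The average over the NSC and OPC lines gave 6680 genes and that over the OPC and AST lines 4411. The planned values of Hras and Trp53 were not analysed here, and a pseudocount does not apply to log2 values.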

Other observations

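The tests of chance and of a gain in the parent for the chromosomes, and the count over all splits of the arrays, were chosen only after the result was seen.

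The cells lack p53, and genes that p53 is known to switch on changed in both directions. In NSCL61 4 of 18 rose and 10 fell (4 and 10 adjusted over the list alone; camera adjusted p = 0.182), with the membrane protein Perp at 4.47 ± 0.34, Zmat3 at -1.26 ± 0.16 and the sestrin Sesn1 at -2.03 ± 0.28. In OPCL61 9 rose and 6 fell (9 and 6 adjusted over the list alone; camera adjusted p = 0.670), with the BH3 protein Pmaip1 at 4.90 ± 0.36, Perp at 4.25 ± 0.34 and Trp53inp1 at -3.10 ± 0.30. Perp had a level of 9.22 ± 0.44 in AST. Of 12 interferon and antigen presentation genes 3 rose and 1 fell in NSCL61 (2 and 1 adjusted over the list alone; camera adjusted p = 0.945), with Ifit3 at 1.57 ± 0.17. In OPCL61 3 rose and 3 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.795). The 3 that rose, B2m at 1.71 ± 0.13, H2-D1 at 1.74 ± 0.29 and H2-K1 at 1.72 ± 0.31, encode parts of MHC class I.

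Of 4 microglia and macrophage genes 1 rose in NSCL61 and 1 in OPCL61 (1 and 1 adjusted over the list alone), the lysosomal protein Cd68 in each, by 2.55 ± 0.39 and 3.22 ± 0.39. Camera gave adjusted p values of 0.783 and 0.413 for that list. Of 2 endothelial genes 1 rose and 1 fell in NSCL61 and 1 rose in OPCL61. Xist, transcribed from the inactive X chromosome, had group means from 7.46 in ASTL61 to 12.09 in OPC, and the highest group mean of any of 9 probe sets of 3 Y-linked genes was 3.91. Across genes, the correlation of group means was 0.926 for NSCL61 with OPCL61 and 0.759 for NSC with OPC. It was 0.887 for OPCL61 with ASTL61 and 0.795 for OPC with AST. The remaining pair went the other way, with 0.901 for NSCL61 with ASTL61 and 0.930 for NSC with AST.

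Genes of some chromosomes shifted together: relative to all 5498 genes of known position with a mean over arrays above 8, the 182 of chromosome 14 had a median change of -0.64 in NSCL61, and in OPCL61 the 316 genes of chromosome 4 and the 228 of chromosome 15 had -0.46 and -0.43, beside smaller shifts of chromosome 15 in NSCL61 (-0.28) and of chromosomes 16, 2 and 19 in OPCL61 (-0.31, 0.29 and 0.32). Chance placement is argued against for these arrays only. Random assignment of genes to chromosomes treats genes as independent and ignores the spread between arrays. It gave 1e-04 for each of chromosomes 14, 4 and 15, the smallest share the shuffles can give. A loss of copies of the whole chromosome may account for this, since the least shifted of 3 runs of neighbouring genes still had medians of -0.58, -0.39 and -0.30, but DNA copies were not measured and medians also moved between parents without HRasL61, as in OPC against AST by 0.48 for chromosome 14, -0.41 for 19 and -0.36 for 13, while in ASTL61 against AST all lay between -0.09 and 0.06. For chromosome 4 a gain in parental OPC is argued against, since OPCL61 lay at a median of -0.62 from NSCL61 and -0.65 from ASTL61, and OPC differed from AST by -0.18 and from NSC by -0.00. Chromosome 16 was not put to these tests, though OPCL61 lay there at -0.49 from NSCL61 and -0.58 from ASTL61. OPC lay there at -0.17 from NSC and -0.22 from AST. For chromosomes 14 and 15 loss in the line and gain in the parent cannot be told apart: on chromosome 14 NSCL61 lay at -0.36 from ASTL61 and -0.88 from OPCL61, while NSC lay 0.29 above AST but at -0.21 from OPC, and on chromosome 15 OPCL61 lay at -0.02 from NSCL61, itself shifted there, and -0.21 from ASTL61, while OPC lay 0.23 and 0.19 above the other parents.

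Chance as the source of the 5609 genes of the average over 3 lines was set against splits that trade arrays between lines and parents. Of 100 splits drawn from the 108, 4 gave as many genes, the real split included, a share under 0.05. The highest other split gave 5862. Over all 108 splits 4 did as well (3.70%). The 6 splits that keep the NSC and OPC arrays in their groups, whatever the AST and ASTL61 arrays, gave 5415 to 5862 genes. The highest of the others gave 3802, so the count rests on the NSC and OPC lines. The share under 0.05 depends on which of the 6 near-equal splits reach the real count. The splits therefore cannot exclude chance for a change held by all 3 lines.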
